A study of Mus musculus with 12 samples.

How the data were processed

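RNA from luminal and basal mouse mammary gland cells was measured in 12 libraries. They fall into 4 groups of 3: luminal wild type, luminal G9a conditional knockout, basal wild type and basal G9a conditional knockout, as the deposited cell type and genotype labels give them. Each library title holds a number (250, 251 and 669 in knockout libraries, 252, 258 and 668 in wild-type libraries), and each number occurs once in luminal and once in basal cells. The title numbers 250, 251, 252, 258, 668 and 669 are called A to F in that order. Nothing in the labels says that the numbers stand for separate animals, so the p-values measure the spread between these samples, which may be technical. How the cells were separated is not given in the sources used here.

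Total RNA was DNase-treated and made into stranded, ribosomal RNA-depleted libraries, which were sequenced as 125-bp single reads, per the labels' protocols. Trimmomatic 0.36, TopHat2 2.1.1, featureCounts 1.6.0, DESeq2 1.26.0 and the mm10 build are named, per the submitters' processing notes, with no role or order. The strand setting, the gene annotation and the treatment of reads with several matches are not given in the sources used here. The deposited values are raw counts per gene that the authors had not normalized, and they were used as deposited. Of 27177 lines, 2 malformed ones, with no gene name and a missing value, were left out, which leaves 27175 genes. The RefSeq annotation of GRCm38, the assembly that mm10 denotes, was searched for the 850 lines with an identifier alone. It held none of them, so these lines kept the identifier as their name. Of all identifiers 25273 matched that annotation, as did 16505 of the 17188 tested genes, and coordinates are from it. Reads of close paralogs and of overlapping or antisense genes may have been shared or split by the counting, so values of such genes are given as uncertain. Counts per gene sum over all exons and do not measure endogenous retrovirus families.

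Library totals ran from 68619684 to 87158270 counts. A count of 0 allows up to 3 counts per library, or 0.0324 to 0.0458 CPM (counts scaled to the effective library total). Folds against a group with 0 counts were computed against that floor of 3 counts per library and are lower bounds. Floors and counting intervals cover counting error only.

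Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 after TMM normalization and the filterByExpr filter (minimum count 10, minimum total 15). All 12 libraries entered one model with a mean per group, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. For single genes, called or not called refers to this main edgeR test unless another test, setting or adjustment is named. The contrasts were knockout against wild type in luminal cells, the same in basal cells, the difference of these effects, and luminal against basal wild type. Levels are TMM-normalized CPM, given as mean ± SD of 3 libraries. On simulated counts with 200 changed genes, the test recovered 57% of 4-fold and 7.14% of 2-fold changes in the luminal contrast, 59.6% and 9% in the basal one, 37.4% and 2.02% in the difference, and 58% and 8.25% between cell types.

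Before the data were examined, the comparisons with their tests across genes, 39 gene lists, the rule for named genes and most alternatives were fixed. Which lists the text describes, and most tests of explanations and hypotheses, were chosen or changed after values were seen. Lists cover pathways, cell type markers, sample quality and other cells that a gland can hold, and 35 had the 3 tested members required. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with adjustment over the lists of a comparison, again with an estimated correlation, and with fry. Members called were counted over all genes and adjusted over the list alone.

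The rule names Ehmt2, then, among called genes with a mean of at least 1 CPM in the higher group and no overlap between the 3 libraries of each group, the 10 largest rises and the 10 largest falls. Unnamed clones and predicted genes were excluded. It adds up to 4 members with the smallest p of each list described, and the 10 called genes with the smallest p for the difference. Between cell types it names up to 4 members of 4 epithelial marker lists and the 3 largest rises and falls. For lists of other cells it also names up to 4 members with the highest mean CPM. Of the genes that the rule selects, 1 is not reported here.

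Alternatives were RLE and upper quartile scaling, no filter or a filter of 1 CPM in 3 libraries, a term for the series of the title number, DESeq2 1.42.0, limma-voom, the title number as a block, each cell type alone, and each library left out in turn. Leaving out both C libraries was added after the data were seen, as were the splits of title numbers for genes and signs shared by the cell types.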

Results

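Gene counts were compared between mammary gland cells of wild-type mice (WT) and libraries labelled as conditional knockout (cKO) of G9a, a histone methyltransferase encoded by Ehmt2. Luminal cells line the ducts and alveoli and basal cells form the contractile outer layer. Each of the 4 groups held 3 libraries, with totals from 68619684 to 87158270 counts. The first principal component, 75.9% of the variance, separated luminal from basal libraries. Same-group libraries differed by far more than counting noise, with a chi-square per gene of 117 to 513, and no library was a copy of another. The highest values, 495 to 513, were those between WT C and the other WT libraries of its cell type. The letters A to F stand for the 6 title numbers in ascending order, and each letter has 1 luminal and 1 basal library. Title numbers fall into a series below 300, with 4 numbers, and one above 600, with 2, which holds 1 WT and 1 cKO library per cell type and so gives no value of its own. With a term for the series 200 luminal, 408 basal and 56 difference genes were called, beside 266, 526 and 87 without it.

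Ehmt2 (chromosome 17, 34898463 to 34914073, GRCm38) was not lower in libraries labelled cKO. Luminal cKO libraries had 217.6, 237.9 and 246.4 CPM for A, B and F, and luminal WT libraries 198.4, 202.3 and 277.9 CPM for C, D and E. Basal cKO libraries A, B and F had 157.6, 170.2 and 151 CPM and basal WT libraries C, D and E had 141.8, 130.6 and 120.3 CPM. The log2 fold change was 0.05 (SE 0.16) in luminal cells, with an edgeR adjusted p of 0.956, and 0.29 (SE 0.16) in basal cells, with an adjusted p of 0.424. Leaving out one library took the luminal value from -0.04, without luminal WT C, to 0.22, and it was also negative, at -0.03, without luminal WT D. The count sums all exons and the labels do not give the deleted part, so it does not check the genotype labels, and every direction below rests on them.

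**Figure D1:**
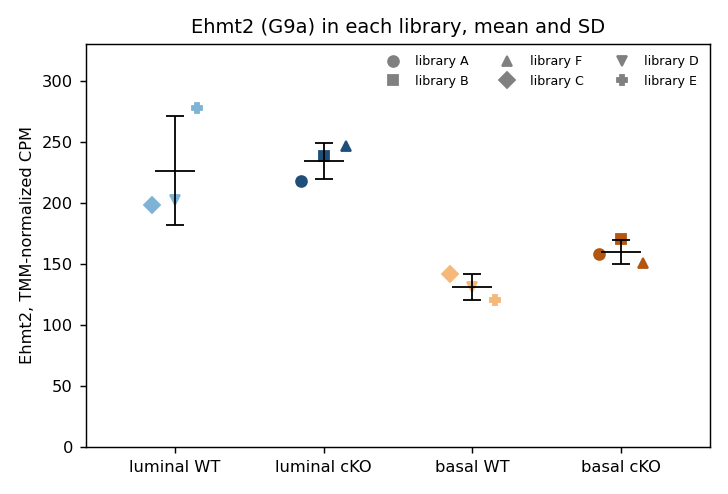
TMM-normalized CPM of Ehmt2 in each library, with group means (wide bars) and SD (error bars, n = 3) and one symbol per title number. Means were 226 in luminal WT, 234 in luminal cKO, 131 in basal WT and 160 in basal cKO.

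Luminal and basal WT libraries were compared to set the cell types apart. Myh11, the smooth muscle myosin heavy chain, had 0.587 ± 0.194 CPM in luminal WT and 1320 ± 404 CPM in basal WT (SD, n = 3), and Mylk (log2 fold change -10.40), Cnn1 (-9.46) and Dll1 (-6.82) were lower in luminal WT too. The luminal keratin Krt19 had 1250 ± 213 CPM in luminal and 7.13 ± 2.35 CPM in basal WT, Epcam 1880 ± 348 and 334 ± 56.3, Prom1 428 ± 153 and 21.5 ± 5.81, and Cldn7 107 ± 21.7 and 4.31 ± 0.553. Single genes of luminal progenitors were higher in luminal WT, though their list did not pass with an estimated correlation (adjusted p 0.724), among them Cd14 (215-fold), Kit (105 ± 95.5 CPM in luminal WT), Elf5 (53.4 ± 56.8) and Aldh1a3 (876 ± 735), as were the hormone-sensing markers Prlr (684-fold), Foxa1 (408-fold), Cited1 (315-fold) and Cxcl15 (1100-fold). The prolactin receptor Prlr had an adjusted p of 7.9e-08. Without luminal WT C the log2 fold change went from 7.01 to 5.94 for Kit, from 7.05 to 5.68 for Elf5 and from 6.74 to 5.82 for Aldh1a3. It was 7.78 for Aldh1a3 without basal WT C, and for Foxa1 it went from 8.67 to 8.06 without luminal WT D.

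Of 17188 tested genes, edgeR called 8980 between the WT cell types, 4478 higher and 4502 lower in luminal cells. Ifnl3 (at least 240-fold), Olfm4 (at least 125-fold) and Cntn4 (at least 115-fold) had no count in basal WT, and Uts2b (at least 436-fold), Sobp (at least 343-fold) and Usp13 (at least 129-fold) had none in luminal WT. All 23 myoepithelial markers were called lower in luminal WT (camera adjusted p 4.67e-23, and 0.0443 with an estimated correlation), all 23 also adjusted over the list alone. General luminal markers were called higher for 13 of 17 (1.73e-10, and 0.0443), hormone-sensing markers for 14 of 16 with 1 lower (3.15e-11, and 0.0443), and progenitor markers for 8 of 12 (0.00216, and 0.724). Adjusted over the list alone, these counts were 13, 14 with 1 lower, and 9. Lower lists were Wnt targets and ligands (1.94e-05, and 0.0443, 9 of 12 called lower and 1 higher), matrix and mesenchymal genes (0.000158, and 0.0689, 10 of 14 lower and 1 higher) and genes derived from retroelements (0.049, and 0.41, 5 of 9 lower), with the same counts adjusted over the list alone. The Krt5 level, a basal keratin, was 156 CPM in luminal WT C and 0.6526 to 4.175 CPM in the other luminal libraries.

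G9a deletion in the developing gland is the subject of the series, and luminal cells were compared first. Aim2, a sensor of cytosolic DNA, rose from 3 ± 2.3 CPM in luminal WT to 71.7 ± 11.8 CPM in luminal cKO (log2 fold change 4.58, and 5.40 without WT C; n = 3). The reproductive homeobox gene Rhox5 rose from 0.061 ± 0.0103 to 11.6 ± 4.6 CPM and the RNA export factor gene Nxf3, like Rhox5 on the X chromosome, from 0.0327 ± 0.0218 to 13.4 ± 7.71 CPM. The non-coding RNA Platr14 rose from 0.136 ± 0.109 to 30.4 ± 4.02 CPM. Dlg2, a synaptic scaffold gene, fell from 9.16 ± 2.71 to 0.277 ± 0.0812 CPM, and Zfp809, a zinc finger gene of retroviral silencing, from 35.1 ± 14.1 to 14.7 ± 3.23 CPM.

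The adjusted p was 2.91e-05 for Rhox5 (X, 37754608 to 37808878), 0.000111 for Nxf3 (X, 136071523 to 136139579), 0.0001 for Platr14 (2, 104559184 to 104571429), 0.000683 for Aim2 (1, 173349547 to 173466040) and 0.000103 for Dlg2 (7, 90476188 to 92449246). Muc19, a mucin gene, was at 10.9 ± 9.78 CPM in luminal cKO and had no count in WT. Muc19 is uncertain together with Smgc (at least 38.2-fold), since the annotation treats them as one locus. Scrn1 (at least 45.9-fold), Soga3 (at least 27.6-fold) and the uncertain paralog Tcp11x2 (at least 25.2-fold) likewise had no count in WT. Zkscan2, with 3 counts in WT, had a ratio of 276 with a 95% counting interval of 94.3 to 1340. The antisense gene Ptprtos had a ratio of 238 with an interval of 65.8 to 1960 and is uncertain because the strand setting is not given. The other falls were Osr1 (13.8-fold), Fst, an activin-binding protein (6.6-fold), Nqo1, a quinone reductase (4.03-fold), Sdc3 (3.97-fold), Nes (3.8-fold), Tnfrsf11b, a decoy receptor for RANKL (3.19-fold), Sh2d5 (2.81-fold) and Lysmd4 (1.9-fold). The log2 fold change went from -3.78 to -4.51 for Osr1 without cKO F and from -2.72 to -2.05 for Fst without WT C.

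In all, 266 genes were called in luminal cells, 247 higher and 19 lower in cKO, and 186 of them met the other criteria for naming. DESeq2 called 785 (639 higher and 146 lower), and the luminal libraries alone gave 68 (66 and 2). WT and cKO libraries did not overlap for 16.5% of tested genes, where chance gives 10%. The count was 98 without cKO B, 144 without cKO F, 459 without WT C, 137 without WT D and 120 without WT E, and 1067 (698 higher and 369 lower) without both C libraries. Of the 10 named falls, 8 lost the call without cKO A, 9 without cKO B, 8 without cKO F, 5 without WT D and 5 without WT E, while of the 10 rises Tcp11x2 lost it without cKO B (adjusted p 0.0658). With the luminal libraries alone 9 falls and 3 rises, Muc19 (0.0513), Smgc (0.0809) and Soga3 (0.0712), lost the call. Falls also lost it with limma-voom (6, with or without the replicate block), the term for the series (5), the filter of 1 CPM (3) and no filter (1). Dlg2 kept it in each of these alternatives (adjusted p up to 0.00594).

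All 48 interferon-stimulated genes had negative fold changes in luminal cells, with a median log2 of -1.05. Dhx58, an RNA sensor, was at 41.7 ± 6.68 CPM in WT and 10.9 ± 5.49 CPM in cKO, Irf7 at 25.8 ± 5.45 and 8.25 ± 3.02, Ifi44 at 75.4 ± 10.3 and 20.4 ± 7.48, and Zbp1 at 24.1 ± 3.25 and 8.4 ± 2.91. No member was called by edgeR over all genes, with 25 at an unadjusted p under 0.05, while 14 were lower adjusted over the list alone, DESeq2 called 7 and limma-voom 2. Without both C libraries edgeR called 11, all lower, but without luminal WT C alone it called 0. It called 1 without cKO A and 1 with no filter, and limma-voom with the replicate block called 3. The list passed camera (adjusted p 7.85e-19), and its adjusted p was 0.9 with an estimated correlation and 0.427 with fry.

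**Figure D2:**
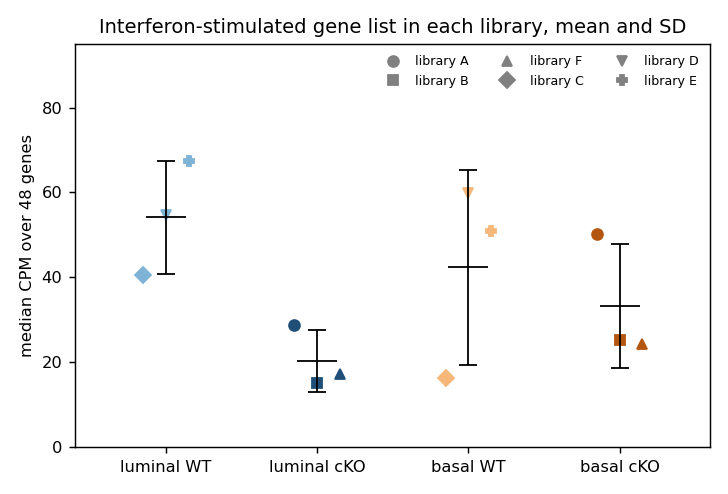
Median CPM over the 48 interferon-stimulated genes in each library, with group means (wide bars) and SD (error bars, n = 3). Luminal WT lay at 54.2 ± 13.4, luminal cKO at 20.3 ± 7.32, basal WT at 42.4 ± 23 and basal cKO at 33.2 ± 14.7.

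Myoepithelial markers were the other list that passed in luminal cells (camera adjusted p 0.000152, lower for 21 of 23 members). Their adjusted p was 0.9 with an estimated correlation, 0.532 with fry and, with camera, 0.523 without WT C. This list holds Krt5 and Lgr5. Of its members Lgr5, a receptor for R-spondins, fell from 0.676 ± 0.202 to 0.108 ± 0.0554 CPM, and 6 were lower adjusted over the list alone. Krt5 was at 54.5 ± 87.9 CPM in WT and 1.61 ± 0.846 CPM in cKO, the WT mean resting on C, Tpm2 at 48.5 ± 40.2 and 11.3 ± 1.91, and Oxtr at 2.17 ± 1.9 and 0.626 ± 0.171. All 10 splits of the 6 luminal libraries into 3 and 3 called at least 2 lists at the preset correlation.

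Single members of other lists passed while the lists did not. Among milk genes (adjusted p 0.0781) Wap, a whey protein, rose from 0.0339 ± 0.0588 to 3.19 ± 2.49 CPM, while Csn1s1 (9.2 ± 15.3 and 69.8 ± 37.4 CPM), Csn1s2b and Olah were not called. The WT levels of Wap and Csn1s1 varied by more than their means. Over alternatives the log2 fold change ran from 5.69 to 10.94 for Wap and from 2.35 to 7.61 for Csn1s1. Wap lost its call in 5 of 16 alternatives, and Csn1s1 was called in 4 of 16. Among 21 genes of the p53 pathway, apoptosis and senescence (0.521) the cell cycle inhibitor Cdkn2a rose from 0.0503 ± 0.0374 to 4.52 ± 3.87 CPM. Its neighbour Cdkn2b was at 3.24 ± 0.841 and 12.2 ± 6.01 CPM, Plk2 at 417 ± 64.4 and 241 ± 39.4, and Sesn2 at 15.6 ± 6.72 and 9 ± 1.72. The main edgeR test called none of the 3, while Plk2 was called in 4 of 16 alternatives and Cdkn2b in 2 of 16. Adjusted over the list alone, 2 of these 21 genes were higher and 1 lower. Among 26 imprinted genes (0.221) Peg3 rose from 2.67 ± 1.99 to 25.1 ± 8.81 CPM, and Igf2 (0.611 ± 0.46 and 2.81 ± 1.62), Peg10 and Ndn were not called. Among 24 nucleic acid sensors (0.168) Aim2 alone was called by the main edgeR test, with 1 higher and 2 lower adjusted over the list alone. Irf3 was at 32.6 ± 11.5 and 19.9 ± 1.86 CPM and was called in 2 of 16 alternatives. Wnt targets and ligands had an adjusted p of 0.0781, with Lgr5 called and Wnt10a, Notum and Wnt6 all under 0.2 CPM in both groups. Adjusted over the list alone, 1 milk gene and 1 imprinted gene were higher and 3 Wnt genes lower. Without WT D, 4 of the 6 called members named from lists were lost, 3 without cKO B, 2 without cKO F, 2 without WT E, 1 without cKO A, 4 with the luminal libraries alone and 1 (Lgr5) with limma-voom.

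Of 32 genes on the germline list 14 were tested, and edgeR called none of them in luminal cells. The reproductive homeobox gene Rhox5, which was called, is not among these 14. Of the 14, 2 had an unadjusted p under 0.05, 1 passed adjusted over the list alone, DESeq2 called 1 and limma-voom 0. Without cKO A edgeR called 1. Sycp3 was at 1.89 ± 0.699 and 3.6 ± 0.721 CPM, and the list had an adjusted p of 0.533. Syce1 was at 0.336 ± 0.336 CPM in cKO and had no count in WT, Piwil2 at 1.25 ± 0.526 and 0.836 ± 0.123, and Tex15 at 24.9 ± 10.8 and 37.3 ± 5.23. Genes of histone methylation on lysine 9 of H3 had an adjusted p of 0.281, with Kdm4a at 76.2 ± 13.9 and 52.5 ± 6.59 CPM, Kdm3b at 136 ± 5.41 and 101 ± 0.682, Suv39h1 at 11.2 ± 1.66 and 8.83 ± 1.85 and Pphln1 at 18.5 ± 3.47 and 15.6 ± 0.511. Of markers of other cells, MHC class II genes had positive fold changes for 7 of 7 members (0.0781). Of these, H2-Ab1 was at 1.68 ± 1.28 and 8.39 ± 0.759 CPM, H2-DMb1 at 10.7 ± 2.98 and 15.3 ± 8.33, H2-DMa at 2.41 ± 0.584 and 2.91 ± 1.43, Cd74 at 1.54 ± 1.51 and 2.28 ± 0.92, H2-Aa at 0.386 ± 0.0953 and 0.774 ± 0.457 and H2-Eb1 at 0.437 ± 0.254 and 0.783 ± 0.479. Macrophage and dendritic cell markers had an adjusted p of 0.866, and Itgam, an integrin subunit, rose from 0.0333 ± 0.0228 to 0.441 ± 0.189 CPM. Cd68 had a log2 fold change of -0.48 (35.6 ± 19.5 CPM in WT, 25.6 ± 2.83 in cKO), which became 0.05 without WT C, Csf1r was at 3.27 ± 2.78 and 2.26 ± 0.317, Lyz2 at 0.382 ± 0.335 and 0.281 ± 0.253, C1qa at 0.123 ± 0.0818 and 0.0477 ± 0.0826 and Fcgr1 at 0.0378 ± 0.0177 and 0.00989 ± 0.0171. The general leukocyte list had an adjusted p of 0.839, a positive mean and test and a negative median, and its members Fyb, Ptprc, Cd53, Coro1a and Cd37 stayed under 0.3 CPM in both groups. Its most abundant member, Cytip, was at 340 ± 406 and 268 ± 158 CPM, with a log2 fold change of -0.34, which was 1.34 without WT C and 0.21 with limma-voom. Adjusted over the list alone, 1 MHC class II gene and 1 macrophage gene were higher, and the count was 0 for the leukocyte and histone methylation lists, where 0 and 2 genes had an unadjusted edgeR p under 0.05.

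In basal cells Rhox5 had no count in WT and 22.1 ± 2.96 CPM in cKO, a rise of at least 574-fold (n = 3). Nxf3 rose from 0.0547 ± 0.0476 to 109 ± 19.9 CPM and Aim2 from 0.0458 ± 0.0177 to 33.5 ± 5.7 CPM. The cytokine gene Il1a rose from 0.564 ± 0.332 to 27.7 ± 10.9 CPM and Csn3, kappa-casein, from 1.14 ± 0.475 to 35.4 ± 7.31 CPM. Prrx1, a mesenchymal homeobox gene, fell from 58.5 ± 30.6 to 1.46 ± 0.629 CPM, and Chl1, a cell adhesion gene, from 64.3 ± 17.9 to 2.77 ± 1.31 CPM.

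Adjusted p-values were 5.82e-06 for Rhox5, 1.06e-05 for Nxf3, 1.25e-05 for Aim2, 0.000243 for Prrx1 (1, 163245119 to 163315145) and 0.00202 for Chl1 (6, 103510584 to 103733038). Further rises from no count in WT were Syndig1 (at least 113-fold), Ptprq (at least 45.9-fold) and, uncertain because of close paralogs, Akr1c13 (9.96 ± 2.26 CPM in cKO), Rhox2d (at least 83.3-fold), Rhox2g (at least 61.2-fold), Rhox2h (at least 44.5-fold) and Raet1d (at least 32.9-fold). Brinp1 (4, 68761372 to 68954397) fell from 12.6 ± 3.86 to 0.0237 ± 0.0245 CPM, Nkain2 from 3.74 ± 0.76 to 0.0163 ± 0.0282, Frmpd4 from 14.9 ± 3.44 to 0.142 ± 0.0956, Aff2 from 4.96 ± 2.22 to 0.0834 ± 0.0774, Klf12 36.7-fold, Thsd7a 31.1-fold and Fat3, an atypical cadherin, 26.8-fold. Nkain2 had 4 counts in basal cKO, all in F, so its log2 fold change of -7.74 rests on F, without which cKO has no count. Without F the log2 value went from -8.97 to -9.91 for Brinp1 and from -5.87 to -6.89 for Aff2, and without cKO B from -6.69 to -7.38 for Frmpd4. Robo2, a Slit receptor, fell from a WT level of 41.9 ± 61.2 CPM that varied by more than its mean, with a log2 fold change of -7.16, which was -4.47 without WT C and -8.48 without cKO F.

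In all, 526 genes were called in basal cells, 339 higher and 187 lower in cKO, and groups did not overlap for 22.6% of genes, where chance gives 10%. DESeq2 called 1307 (714 higher and 593 lower). The count was 240 without cKO A, 239 without cKO B, 303 without cKO F, 1070 without WT C and 202 without WT D, and 2096 (1169 higher and 927 lower) without both C libraries. The 10 named rises kept their call without any library, while of the 10 falls Robo2, Klf12 and Fat3 lost it without cKO A, B or F, Klf12 and Fat3 without WT D and Robo2 without WT C (highest adjusted p 0.121, 0.0621 and 0.103 over all alternatives). Robo2 lost it also with limma-voom (0.0907) and with the term for the series (0.0635).

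**Figure D3:**
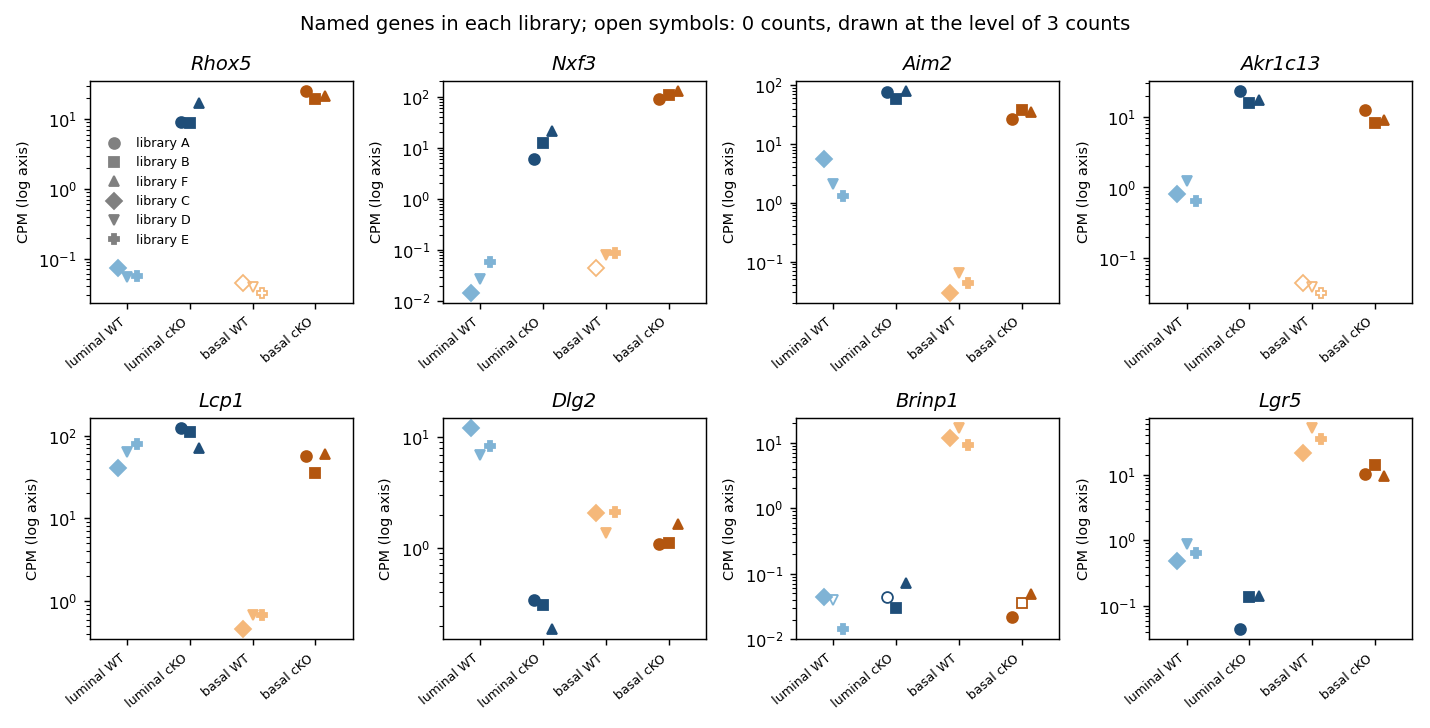
CPM (log axes) of 8 genes in each library, one symbol per title number, with open symbols for libraries at 0 counts drawn at the level of 3 counts. Rhox5, Nxf3, Aim2 and Akr1c13 were higher in all cKO libraries of both cell types, Lcp1 was called in basal cells, Dlg2 in luminal cells, Brinp1 in basal cells and Lgr5 in both.

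Inflammatory genes of the NF-kB pathway had positive fold changes in basal cKO for 25 of 31 members. The camera adjusted p was 0.000201, and 0.823 with an estimated correlation, while the fry adjusted p was 0.244. Il1a and Csf2 (0.322 ± 0.127 to 3.2 ± 1.96 CPM) rose, 5 were higher adjusted over the list alone, and Ccl5 (0.582 ± 0.442 and 7.12 ± 3.2 CPM) and Tnf (1.94 ± 1.49 and 12.2 ± 4.19) were not called. Imprinted genes (0.0325, and 0.266 with an estimated correlation) held 4 that rose, Grb10, a growth factor receptor adaptor, from 18.4 ± 5.4 to 104 ± 14.9 CPM, Mest from 8.16 ± 3.28 to 31.3 ± 12.8, Ndn from 0.155 ± 0.0536 to 1.97 ± 0.0665 and Mkrn3 from 0.881 ± 0.201 to 2.97 ± 0.338, with 5 higher and 1 lower adjusted over the list alone. Squamous keratinocyte genes (0.0463, and 0.858) had positive fold changes for 12 of 13, with Sbsn rising from 6.4 ± 2.04 to 26.4 ± 10.9 CPM as the 1 called gene in either count, and Dmkn, Krt16 (32 ± 17.1 and 66.3 ± 8.3 CPM) and Sprr1a not called. General luminal markers (0.037, and 0.823) fell for Cldn7, a tight junction claudin (4.31 ± 0.553 to 1.4 ± 0.296 CPM), Prom1 (21.5 ± 5.81 to 5.74 ± 1.79) and Krt19 (7.13 ± 2.35 to 2.33 ± 0.203), with 4 lower and 2 higher adjusted over the list alone, and Spint1 was not called. Interferon-stimulated genes (0.0411, and 0.901, 36 of 48 negative) had no member called by edgeR, 11 at an unadjusted p under 0.05, 0 adjusted over the list alone, 3 by DESeq2, 0 by limma-voom and 1 by limma-voom with the replicate block. Without WT C edgeR called 10 of them, 9 lower and 1 higher, and without both C libraries 13, 12 lower and 1 higher. Trim30a was at 13.5 ± 10.2 and 55.2 ± 20.6 CPM, Usp18 at 49.9 ± 32.3 and 13.4 ± 8.48, Ddx58 at 246 ± 118 and 130 ± 36.8 and Lgals3bp at 18 ± 5.07 and 9.17 ± 2.21.

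Markers of other cells moved in basal libraries as well. Pericyte markers were lower for 6 of 6 (adjusted p 0.0111, and 0.266 with an estimated correlation), with Notch3 falling from 1.17 ± 0.0854 to 0.492 ± 0.0399 CPM, 3 lower adjusted over the list alone, and Rgs5, Pdgfrb (2.45 ± 1.11 and 0.872 ± 0.178), Cspg4 and the most abundant, Mcam (135 ± 91.3 and 83.8 ± 25.2), not called. Notch3, the only one called, was far higher in luminal libraries, at 95.8 CPM in WT and 116 CPM in cKO. Its fall in basal libraries therefore does not point to pericytes. Adipocyte markers (0.0274, and 0.266) held Lep, leptin, which rose from 0.144 ± 0.076 to 4.43 ± 0.999 CPM, and 2 were higher adjusted over the list alone. Fabp4 was at 22.2 ± 20.9 and 115 ± 82.4 CPM, Plin4 at 10.1 ± 3.79 and 9.72 ± 1.48, Lpl had a log2 fold change of -0.35, which was 0.14 without WT C and 0.03 without cKO B, and Retn one of 0.20, which was -0.31 without WT C and -0.15 without cKO B. Neutrophil markers (0.0274, and 0.266) held Camp, which rose from 0.0631 ± 0.0405 to 1.46 ± 0.791 CPM and was the 1 called in either count, while S100a8, Cxcr2 and S100a9 stayed under 1 CPM in both groups. S100a9 had a log2 fold change of 1.82, which was -1.40 without cKO B. General leukocyte markers (0.677) such as Ptprc, Cd53, Fyb, Cd37, Coro1a, Cd52 and Laptm5 stayed under 0.4 CPM, and Cytip was at 0.834 ± 0.459 and 0.928 ± 0.353. Macrophage and dendritic cell markers were positive for 7 of 8 (camera p 0.0409, adjusted 0.119), with Cd68 at 71.8 ± 44.9 and 156 ± 3.2 CPM in WT and cKO, Lyz2 at 0.181 ± 0.0815 and 1.33 ± 0.841, Csf1r at 0.504 ± 0.27 and 0.467 ± 0.076, and C1qa, Fcgr1 and Itgam under 0.3 CPM. None was called by the main edgeR test, and Lyz2 was the 1 higher adjusted over the list alone. Among alternatives Cd68 was called in 2 of 16 and Lyz2 in 1 of 15. MHC class II genes (0.582) had Cd74 at 6.22 ± 3.53 and 19.7 ± 2.62 CPM, H2-Ab1 at 3.15 ± 2.02 and 3.55 ± 0.572, H2-DMb1 at 1.89 ± 0.456 and 1.13 ± 0.177, H2-Aa at 1.21 ± 0.478 and 1.63 ± 0.276 and H2-DMa at 0.472 ± 0.105 and 0.531 ± 0.0487. The main edgeR test called none of these, while Cd74 was called in 3 of 16 alternatives.

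Some list members changed where the list did not pass. The DNA sensing adaptor Tmem173 fell from 14.9 ± 6.8 to 5.01 ± 0.979 CPM beside the rise of Aim2 (nucleic acid sensors 0.176). Cdkn2b rose from 0.399 ± 0.309 to 3.12 ± 0.339 CPM (p53, apoptosis and senescence 0.111; 4 higher and 1 lower over the list alone), with Plk2, Aen and Sesn2 not called. Lgr5 fell from 36 ± 15.1 to 11.3 ± 2.52 CPM (Wnt 0.109; 2 lower over the list alone), with Notum, Nkd1 and Wnt6 not called. Csn3 rose (milk genes 0.439), and Ltf, Btn1a1 and Wap, which had no count in basal cKO and 0.0442 ± 0.0199 CPM in WT, were not called. Greb1, an estrogen-regulated gene, rose from 4.35 ± 1.97 to 25.9 ± 17 CPM (hormone-sensing genes 0.546), while Pgr (4.67 ± 2.59 and 1.57 ± 0.379) and Tbx3 were not called. The lysine demethylase gene Kdm3b fell from 87 ± 10.9 to 46.5 ± 3.85 CPM (histone methylation list 0.299), with Wiz, Fam208a and Kdm4a not called. Asz1, a germline gene, rose from 0.0171 ± 0.0153 to 0.53 ± 0.0788 CPM (0.833), with Piwil2, Dkkl1 and Meiob not called. MHC class I genes (0.0639) had 4 higher adjusted over the list alone, with B2m at 608 ± 145 and 1240 ± 35.9 CPM, H2-D1 at 401 ± 134 and 771 ± 65.3 and the uncertain paralogs H2-Q6 and H2-Q7 not called over all genes. Adjusted over the list alone, 1 milk gene, 1 germline gene, 1 leukocyte gene and 1 hormone-sensing gene were higher, and 3 hormone-sensing genes and 1 histone methylation gene were lower.

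Removal of single basal libraries ended several of these calls. Of the 21 called members named from lists, 13 lost the call without WT D, 10 without cKO F, 8 without cKO B, 7 without cKO A, 7 without WT E and 2 without WT C. Notch3, Tmem173 and Greb1 lost it with limma-voom (adjusted p 0.161, 0.0717 and 0.0703), Krt19 with limma-voom and the replicate block (0.0555), Notch3 and Tmem173 with the basal libraries alone (0.0984 and 0.0629), and Csf2 and Tmem173 with the term for the series (0.0602 and 0.0591). Of the lists, interferon-stimulated genes had an adjusted p of 0.165 without cKO B, 0.502 without cKO F, 0.682 without WT D and 0.529 without WT E, but 1.61e-08 without WT C and 1.08e-05 without cKO A. Squamous genes had 0.129, 0.103, 0.136 and 0.187 without B, F, D and E. General luminal markers had 0.0817 without cKO B, 0.103 without cKO F and 0.704 without WT C. Imprinted genes had 0.108 and adipocyte markers 0.0632 without WT E, and 0.103 and 0.0672 without cKO F, and neutrophil markers 0.0915 without cKO B and 0.0746 without WT C. With fry 4 of the 8 lists passed: adipocyte markers (adjusted p 0.00129) and imprinted genes, pericyte markers and neutrophil markers (0.0171 each). The other 4 did not: NF-kB genes and general luminal markers (0.244 each), squamous genes (0.262) and interferon-stimulated genes (0.683). Of the 10 splits of the 6 basal libraries into 3 and 3, 7 called at least 8 lists at the preset correlation, as the real split did.

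Effects in luminal and basal cells were compared gene by gene. Rhox5, Nxf3, Aim2 and Akr1c13 rose in both cell types and Lgr5 fell in both. In all 47 genes were called higher in both, where independent lists would share 4.87, and 2 were called lower in both, where they would share 0.207. Of the 526 genes called in basal cells, 369 (70.2%) had the same sign in luminal cells, and of the 266 called in luminal cells 188 (70.7%) had the same sign in basal cells. Across all 17188 genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.265 and Spearman's rho 0.154. Luminal and basal libraries share title numbers, so independence is no safe reference, and the 9 other splits of the 6 title numbers into 3 and 3 were used beside it. Taking as many genes of smallest p as were called, they shared 9 to 28 higher genes. They gave the same sign for 63.1 to 78.5% of basal and 62.4 to 79.7% of luminal genes, and r of 0.116 to 0.306. The shares of same sign and r of the real split thus lie within the range of the others. Each of the other splits holds an uneven mix of genotypes, so none is a reference free of a genotype effect.

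The effect itself differed between the cell types for Lcp1 and Lcp2, genes best known from leukocytes. Lcp1, an actin-bundling protein, was at 60.9 ± 19 CPM in luminal WT and 102 ± 28 CPM in luminal cKO, and rose from 0.604 ± 0.127 to 51 ± 13.7 CPM in basal cells (n = 3). Lcp2, a signalling adaptor, rose in basal cells from 0.0513 ± 0.0241 to 15.7 ± 3.09 CPM and stayed under 0.1 CPM in luminal cells. Tnfrsf11b fell in luminal cells from 2.94 ± 0.911 to 0.921 ± 0.397 CPM and rose in basal cells from 6 ± 0.282 to 38.1 ± 12.6 CPM. Its luminal fall (edgeR adjusted p 0.045) lost the call in 10 of 16 alternatives. Hpse2, a heparanase-related gene, rose in luminal cells from 0.105 ± 0.0902 to 0.965 ± 0.182 CPM and fell in basal cells from 5.39 ± 1.89 to 0.526 ± 0.194 CPM.

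The difference of log2 fold changes, luminal minus basal, was -5.65 (SE 0.45, edgeR adjusted p 0.000601) for Lcp1, -7.84 (SE 0.86, 0.00419) for Lcp2, -4.34 (SE 0.52, 0.00497) for Tnfrsf11b and 6.54 (SE 0.80, 0.00565) for Hpse2. Phactr1 (-4.69), Phf21b (-4.53) and Akr1c13 (-8.18, uncertain, fitted against a basal WT level of 0) rose in basal cells. Sytl1 (3.23) and Bicd1 (2.82) fell in basal cells, and Dlg2 (-4.49) fell in luminal cells. All 10 kept the call without any library. In all 87 genes were called for the difference, 56 positive and 31 negative. DESeq2 called 556 (338 and 218), and limma-voom 111, or 267 (155 and 112) with the replicate block as a random effect. Of the 87 genes, 84 were among these 267. With the title number as a fixed replicate block edgeR called 130, and these held 56 of the 87. The term for the series gave 56 (33 and 23). This balance did not hold throughout: positive and negative numbered 293 and 278 without both C libraries, 13 and 14 without basal cKO A or basal cKO B, 12 and 15 without luminal cKO B, 31 and 30 without luminal WT D, 16 and 16 without luminal WT E, and 65 and 65 with the title number as a fixed replicate block. The count was 27 without basal cKO A, luminal cKO B or basal cKO B, 204 and 159 without luminal or basal WT C, 46 without basal WT D, 32 without luminal WT E, 36 and 37 without luminal or basal cKO F, and 571 without both C libraries.

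**Figure D4:**
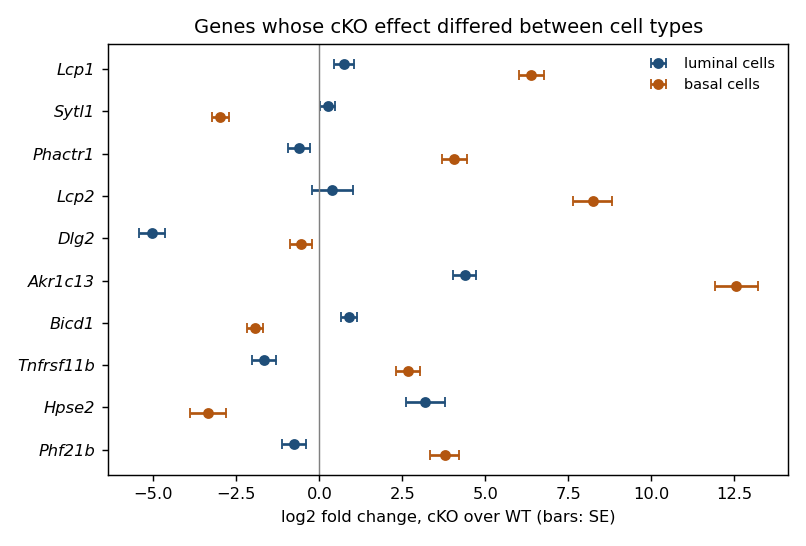
log2 fold change of cKO over WT with SE for the 10 genes with the smallest p for the difference, in luminal (blue) and basal (orange) cells. Lcp1 had 0.74 in luminal and 6.39 in basal cells and Dlg2 -5.04 and -0.55, while the basal value of Akr1c13 was fitted against a WT level of 0 and is no measured size.

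Among lists, none of which passed with an estimated correlation (lowest adjusted p 0.96), the effect was lower in luminal than in basal cells for interferon-stimulated genes (40 of 48 members, camera adjusted p 9.51e-05), NF-kB genes (26 of 31, 0.00115), MHC class I genes (17 of 17, 0.00142) and myoepithelial markers (18 of 23, 0.0186), and higher for general luminal markers (13 of 17, 0.00672). Over all genes 2 general luminal markers were called, 3 adjusted over the list alone, and 1 NF-kB gene was called adjusted over the list alone.

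**Figure D5:**
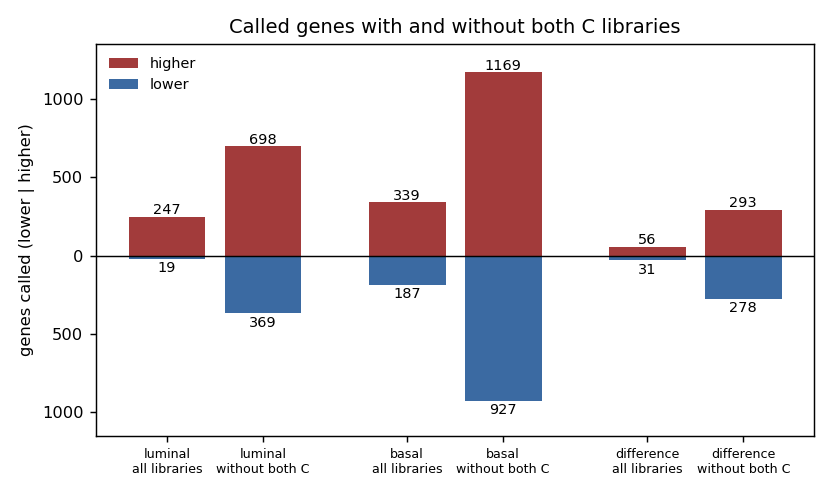
Genes called at an adjusted p under 0.05, with all 12 libraries and without both C libraries, for luminal cells, basal cells and the difference. For luminal and basal cells, up and down are genes higher and lower in cKO. For the difference, they are positive and negative values of the luminal minus the basal effect. Luminal counts were 247 and 19 with all libraries and 698 and 369 without them.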

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

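The tests by splits of the libraries were set before their results were seen, except those on genes higher in both cell types and on shared signs, which were added after, while every test of an explanation weighed here was chosen or changed after the pattern was seen. The share of rises among abundant genes gained its interval condition after the value was known, and the test of both C libraries its condition on single libraries. The leukocyte sum first included Cytip, and the luminal cell test first used a median fold change, before both were replaced.

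For 87 genes the effect of the cKO label differed between luminal and basal cells in the test of the difference itself. Those with the smallest p had differences of log2 fold change, luminal minus basal, of -5.65 for Lcp1, 3.23 for Sytl1, -4.69 for Phactr1, -7.84 for Lcp2, -4.49 for Dlg2, -8.18 for Akr1c13, 2.82 for Bicd1, -4.34 for Tnfrsf11b, 6.54 for Hpse2 and -4.53 for Phf21b. The value of Akr1c13, a gene with close paralogs, was fitted against 0 counts in basal WT and is no measured size. Without both C libraries, 571 genes were called, and 27 without basal cKO A, luminal cKO B or basal cKO B, 46 without basal WT D, 32 without luminal WT E, 36 without luminal cKO F, 37 without basal cKO F, 204 without luminal WT C and 159 without basal WT C.

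The 10 splits of 6 libraries or title numbers into 3 and 3 are too few for a share under 0.05. For genes called, 1 split, the real one, reached the real count in each comparison: 266 in luminal cells with 23 the highest other, 526 in basal cells with 1, 87 for the difference with 0 and 8980 between cell types with 0. The split with 23 set luminal libraries A, D and E against B, C and F. The median of the interferon-stimulated list had a size of 1.05 in the real luminal split and 0.753 as the highest other, so 1 split reached it. For gene lists at the preset correlation, 10 of 10 luminal splits called at least the 2 lists of the real one, with 12 the highest other, and 7 of 10 basal splits at least its 8, with 10 the highest other. These counts of lists are therefore no larger than those of arbitrary splits. The correlation of luminal and basal effects, 0.265, was reached by 2 of 10 splits, with 0.306 the highest other. The 47 genes higher in both cell types were reached by 1 split, the real one, with 28 the highest other. The same sign in luminal cells for 70.2% of basal calls was reached by 7 of 10 splits (78.5% the highest other), and in basal cells for 70.7% of luminal calls by 4 of 10 (79.7%). The shares of same sign are therefore no higher than those of arbitrary splits. The other splits of luminal libraries, basal libraries or title numbers hold an uneven mix of genotypes. They are thus no reference free of a genotype effect. Each other split of the WT libraries mixes luminal and basal libraries in both groups. The cell type difference then lies within the groups, so their 0 calls are no informative reference for the 8980.

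Genes called in luminal cells were mostly higher in cKO, 92.9%. A shift of scale between libraries moves all genes alike. The median log2 fold change of the rises lay 3.26 above that of all tested genes (lower quartile 2.26). This gap cannot decide on scale as the source of their size, since the rises were selected as called. Simulated 2-fold changes were rarely called (7.14%), so called genes lie far from the median in any case. Whether a shift of scale tips the balance of rises and falls stays open as well. The median of all tested genes was -0.03, but the scaling centres the genes and so fixes that value. RLE (93.4% higher) and upper quartile (92.1%) also set a common level. Low counts, at which falls are harder to detect, stay open: of 79 called genes with a mean of at least 10 CPM, 83.5% were higher (95% Wilson interval 73.9 to 90.1). The spread that the C libraries add to their WT groups, luminal and basal, is a candidate explanation that stays open too. The share was 65.4% without both and 84.4 to 97.8% without any other number, but among single libraries it was 80.3% without luminal WT D and 82.8% without luminal WT C, which does not single out C. A loss of repression in cKO would also give more rises, and it was not tested apart from these.

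Interferon-stimulated genes had lower levels in luminal cKO as a list at the preset correlation. No member was called by edgeR over all genes, with 25 at an unadjusted p under 0.05, 7 called by DESeq2 and 2 by limma-voom. Without both C libraries edgeR called 11, all lower, but without luminal WT C alone it called 0. The adjusted p of the list at its estimated correlation (0.683) was 0.9, so whether the list fell depends on the test. At the preset correlation it passed camera whichever luminal library was left out (adjusted p up to 4.98e-12). The number of members called did change with the libraries. Leukocyte RNA in the WT libraries is argued against, since 7 leukocyte genes summed to 0.837 CPM in luminal WT while the list lost 1680 CPM. With Cytip, at 340 CPM in luminal WT and 268 CPM in luminal cKO, the sum was 341 CPM and the first version of this test was undecided. A single library as the source is argued against as well, since the list median nearest 0 on leaving out 1 luminal library was -0.83. A shared state of the 3 WT libraries, such as infection or handling, could give the same values and cannot be separated from genotype by these labels.

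Lcp1, Lcp2 and Aim2, genes used by leukocytes, were higher in basal cKO. Leukocytes as their source are argued against, since the 4 most abundant leukocyte markers summed to 1.57 CPM in basal cKO, where Lcp1 was at 51 CPM. Some markers of macrophages and antigen presentation were nonetheless higher there without being called by the main edgeR test. Cd68 was at 156 CPM against 71.8 in WT, Cd74 at 19.7 against 6.22 and Lyz2 at 1.33 against 0.181. Among alternatives Cd68 was called in 2 of 16, Cd74 in 3 of 16 and Lyz2 in 1 of 15. The macrophage list was positive for 7 of 8 (adjusted p 0.119), while the macrophage receptor gene Csf1r was at 0.467 CPM in cKO and 0.504 in WT and Ptprc at 0.256 and 0.31. Neutrophil markers were positive for 4 of 4 (camera adjusted p 0.0274, and 0.266 with an estimated correlation). Of these Camp was called, at 1.46 CPM in cKO against 0.0631 in WT. Luminal cells in the basal libraries are argued against too, since 17 general luminal markers reached a median of 3.94% of their luminal cKO level and Lcp1 50%. The first version of that test gave a median log2 fold change of -0.40 for these markers in basal cells. Expression in basal cells labelled cKO may remain as a hypothesis, and other cell types were not tested as a source.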

How the results depend on the processing

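Of the tests here, leaving out both C libraries was chosen after the data were seen. DESeq2 called 785 luminal, 1307 basal and 556 difference genes, and the luminal libraries alone gave 68 luminal genes. A term for the series of the title number gave 56 difference genes. Leaving out replicates gave 98 to 1067 luminal, 202 to 2096 basal and 27 to 571 difference genes, the highest each time without both C libraries, and 8058 to 9524 genes between cell types. The luminal count was 98 without cKO B, 120 without WT E, 137 without WT D, 144 without cKO F and 459 without WT C. The basal count was 202 without WT D, 239 without cKO B, 240 without cKO A, 303 without cKO F and 1070 without WT C. The cause of these changes was not tested.

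Ehmt2 in luminal cells ranged from -0.04 without WT C to 0.22. Values that passed no test and turned sign were Cd68 in luminal cells (-0.78 to 0.05, and 0.04 without both C libraries) and, in basal cells, Lpl (-0.68 to 0.14), Retn (-0.31 to 1.18) and S100a9 (-1.40 to 2.41). So did, in luminal cells, H2-DMa (-0.20 to 0.53), Csf1r (-1.02 to 0.33), Lyz2 (-1.49 to 0.57), Cd53 (-0.34 to 1.45) and Cytip (-0.93 to 1.34, and 0.21 with limma-voom, with or without the replicate block). In basal cells they were Plin4 (-0.23 to 0.29, and 0.00 with limma-voom and the replicate block), Cytip (-0.15 to 0.71), Cd53 (-0.57 to 0.08), Fyb (-0.90 to 0.27), Itgam (-0.02 to 0.88), H2-Ab1 (-0.13 to 0.84) and Csf1r (-0.47 to 0.28, and 0.02 with limma-voom or 0.03 with the block). Ranges of these values are over all alternatives, libraries left out included, and the cause was not tested. Luminal lists called numbered 2 to 6 on leaving out replicates, 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 0 with fry (4 unadjusted). Basal lists numbered 4 to 10, 0 with an estimated correlation (4 unadjusted) and 4 with fry (6 unadjusted). The 4 with fry were the adipocyte, imprinted, pericyte and neutrophil lists. The general luminal list in basal cells had an adjusted p of 0.00127 to 0.979, with its direction turned at 0.979, without both C libraries. RLE, upper quartile, the filters and limma-voom kept every count of genes within 1.5 times, but not every named call. Of 10 luminal falls 6 lost the call with limma-voom, 3 with the filter of 1 CPM and 1 with no filter, and of basal genes 3 of 21 list members and 1 of 10 falls lost it with limma-voom. RLE and upper quartile ended no named luminal or basal call. Simulated 2-fold changes were recovered at 7.14% in luminal and 9% in basal cells. Whether depth or the spread between libraries limits this was not tested. Depth does limit low levels, since a count of 0 allows up to 0.0324 to 0.0458 CPM.

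The labels do not say what the title numbers share. Luminal and basal deviations of a number correlated at 0.077 (B) to 0.394 (C), and 11 of 12 libraries matched their own number best, which is a hint from the data alone. With the number as a replicate block, edgeR called 130 difference and 9644 cell type genes. Of the 87 difference genes of the main test, 56 were among these 130. With the replicate block as a random effect, limma-voom called 341 luminal, 641 basal, 267 difference and 10196 cell type genes.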

Other observations

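Of the tests here, those on the X chromosome, on gene span and on neighbouring genes were chosen after the called genes were seen, and the one near Ehmt2 before. The 7 tests were adjusted together. The span test was matched on expression, and pairs with overlapping spans were left out, after first versions had been run.

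Neighbouring genes were often called higher together. Maoa and Maob, paired monoamine oxidase genes on the X chromosome, Cd274 and Pdcd1lg2, ligands of an immune checkpoint receptor, and the imprinted neighbours Ndn and Mkrn3 were both called higher in basal cKO, and Adamdec1 and Adam28 in both cell types. These pairs were picked after their values were seen. In luminal cKO 21 adjacent pairs with spans apart were both higher, where shuffles gave a mean of 3.03 (6.92 times, permutation adjusted p 0.000175), and in basal cKO 40 pairs against 5.86 (6.83 times, 0.000175). With overlapping spans kept, the first version gave 25 and 48 pairs (7.08 and 7.1 times). A candidate explanation is that regions rise together, but tandem paralogs such as Rhox2, Akr1c and Naip genes, which can share reads, are among the pairs. Other pairs are of one family by name, among them Cyp2d, Pcdhb, Ms4a, Aldh1a and Clca genes. So are at least Maoa with Maob, and Adamdec1 with Adam28, of the pairs named above. None of these were removed, so the excess is not shown for unrelated neighbours.

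Genes called higher lay on the X chromosome more often than other tested genes. In luminal cKO it was 17 of 242, or 7.02% against 3.27% (odds ratio 2.24, 95% interval 1.27 to 3.7, Fisher's exact adjusted p 0.00464), and in basal cKO 28 of 335, or 8.36% against 3.22% (odds ratio 2.74, interval 1.78 to 4.09, 5.29e-05). X-linked genes may therefore rise more often, though the Rhox2 paralogs add several of the basal genes and genes in a cluster are not independent.

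Genes called lower in basal cKO had a median genomic span of 60324 bp against 20988 bp for all tested genes, a ratio of 2.87, and 21257 bp for genes called higher. Of 10000 sets matched on mean expression the highest median was 30667 bp, so the permutation p was 1e-04, the smallest they can give (adjusted 0.000175). In the first version, without matching, the highest was 33060 bp. Long genes may fall more often in basal cKO, and RNA quality and nuclear RNA content were not tested as alternatives.

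Strain sequence carried with a targeted allele could change genes near Ehmt2. Within 10 Mb lay 344 tested genes, and the odds ratio of being called was 0.92 in luminal cells (interval 0.294 to 2.2), which leaves a doubling open, and 1.01 in basal cells (0.498 to 1.85), which argues against one. Fisher's exact adjusted p was 1 for both.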
